A study of Mus musculus with 9 samples.

How the data were processed

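Messenger RNA of lumbar dorsal root ganglia from adult C57Bl6 mice was sequenced in 9 libraries, 5 labelled as an inducible conditional knock-out of Prdm12 (icKO) and 4 labelled control with a wild type genotype, 1 month after tamoxifen. Per the labels' protocols, ganglia were dissected in cold buffer and frozen in TRIZOL, RNA was extracted with a column kit, and libraries followed a standard Illumina mRNA-seq protocol. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. Sample groups were taken from the titles and genotype labels.

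The deposited values were raw read counts per gene, 1 table per library with 55536 Ensembl gene identifiers. Per the submitters' processing notes, the authors used bcl2fastq 2.20.0.422, STAR 2.5.2a and featureCounts 1.5.0-p1 with the mm10 genome. The annotation release, the handling of reads that map to several places and whether counting used the strand are not given in the sources used here. Reads of a gene and an overlapping antisense gene could therefore not be separated, and counts of near-identical genes such as the Mrgpr receptors and the globins were treated as uncertain. The identifiers of all 55536 genes were found in a GENCODE annotation on the same build, from which symbols, gene types and positions were taken. No column of other per-sample values was used.

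All statistics were computed from the deposited counts. Genes were kept with the filterByExpr rule of edgeR 4.0.16 applied by group (minimum count 10, minimum total count 15), which left 17258 genes holding 99.9% of the counts of each library. Counts were scaled with TMM factors, given as CPM, the counts scaled to a common library total, and compared between icKO and control with edgeR's quasi-likelihood test with a trended dispersion, in R 4.3.3. The biological coefficient of variation was 0.115. Log2 fold changes are icKO minus control, and the standard error (SE) is the size of the log2 fold change divided by the square root of the F statistic. Benjamini-Hochberg adjusted p-values were computed over all tested genes, with a threshold of 0.05. Log2 CPM for correlations and principal components used a prior count of 2.

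Genes named in the text followed a rule fixed before the data were examined. It took Prdm12, then the 12 higher and 12 lower genes with the largest fold changes among those past the threshold, with a mean of at least 1 CPM and no overlap between the groups, skipping predicted genes, pseudogenes and identifiers without a symbol. Some genes that met the rule are not reported here. Up to 4 members with the smallest adjusted p were then taken from each of 29 gene lists fixed at the same time, holding 364 distinct genes. Of these lists, 27 were tested with camera (limma 3.58.1, preset correlation 0.01) after removing the list with Prdm12 alone and the list of sex-linked genes, and p-values were adjusted over the 27 lists. They covered peptidergic, Mrgprd-type and itch-sensing nociceptors, C-fibre low-threshold mechanoreceptors (C-LTMR) with cold-sensing neurons, A-fibre mechanoreceptors with proprioceptors, ion channels, G protein-coupled receptors, neuropeptides, sensory neuron transcription factors, visceral and other-lineage determinants, the Prdm family with G9a partners, pan-neuronal genes, nerve injury response and immediate early genes. The others covered satellite glia, myelinating Schwann cells, macrophages, lymphocytes with neutrophils, interferon response, endothelial and mural cells, fibroblasts with meninges, spinal cord, skeletal muscle, adipocytes, erythroid cells, axial level Hox genes and the mitochondrial genome. Camera with an estimated correlation and fry were run as alternatives. Single values of Prdm12 and 14 measures of library composition were compared with two-sided exact permutation tests over the 126 splits of 9 libraries into groups of 5 and 4.

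Library totals ranged from 19607740 to 29481589 counts, so that 3 counts, taken as the floor for a gene with no counts, equalled 0.102 to 0.153 CPM. Such floors cover counting error only. On data simulated from the means and depths of these libraries over 17070 genes, with known changes in both directions, the test called 71.9% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 3-fold, and 5.24% of its calls were false. The simulation drew each gene independently, with dispersions fitted to these same data and no library of mixed tissue or sex. Its figures may therefore be better than those for the real libraries. Replicate libraries differed from one another by more than sampling noise, with a chi-square per degree of freedom of 6 to 23.04 over pairs of the same group, so every library was counted once.

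Alternatives fixed before the data were examined were RLE size factors, library size alone, robust dispersion, no count filter, a filter of at least 1 CPM in at least 4 libraries, the replicate number as a block, the Y-linked level as a covariate, 1 surrogate variable (sva 3.50.0), limma voom with and without sample quality weights, DESeq2 1.42.0, other thresholds, and leaving out each library in turn. Fits within libraries of high or low Y-linked counts, fits with the fibroblast or erythroid list as a covariate, and a fit without icKO 4 and control 4 were chosen after seeing the data. Model results were also computed for 100 of the 126 splits of the libraries, the real one included. Plots were drawn with matplotlib 3.10.9.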

Results

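Gene expression was measured by mRNA sequencing in lumbar dorsal root ganglia, the clusters of sensory neuron cell bodies beside the lower spine, of adult mice. Prdm12 encodes a zinc finger transcriptional regulator with a PR domain that is known for its role in nociceptors, the neurons that sense pain. The icKO group held 5 libraries and the control group 4, all taken 1 month after tamoxifen, the drug that triggers the inducible deletion. The icKO libraries held 29481589, 26015905, 28647850, 23878297 and 25432087 counts for replicates 1 to 5, and the control libraries 27970469, 24423500, 27311124 and 19607740 counts for replicates 1 to 4. Pearson correlations of log2 CPM across genes were 0.987 to 0.993 within icKO, 0.986 to 0.989 within control and 0.984 to 0.992 between groups. The first principal component held 26.2% of the variance and did not separate the groups, while the second, with 15.7%, did, with icKO libraries at 2.83 to 16.3 and control libraries at -27.0 to -3.32.

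Loss of the targeted transcript was examined first. Prdm12 fell to 18% of its control level, from 134 ± 20 CPM (SD, n = 4) in control to 24.0 ± 1.41 CPM (SD, n = 5) in icKO, a 5.57-fold difference. Every icKO library, from 22.3 to 26.2 CPM, lay below every control library, from 116 to 163 CPM. The raw counts behind these values were 543 to 696 per icKO library and 3152 to 3491 per control library. The log2 fold change was -2.48 (SE 0.09), with an adjusted p of 2.51e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The two-sided exact permutation test of log2 CPM gave p = 0.00794, the smallest value that groups of 5 and 4 allow. Prdm12 (ENSMUSG00000079466) lies on chromosome 2 from 31640037 to 31655795 on the plus strand of mm10 and is annotated with 1 protein-coding transcript of 5 exons. The labels do not give the deleted exon, so the counts include any exon that remained after deletion. The antisense gene Gm13425 covers its 5′ end up to position 31640589, and reads in the shared stretch could not be assigned to a strand.

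**Figure D1:**
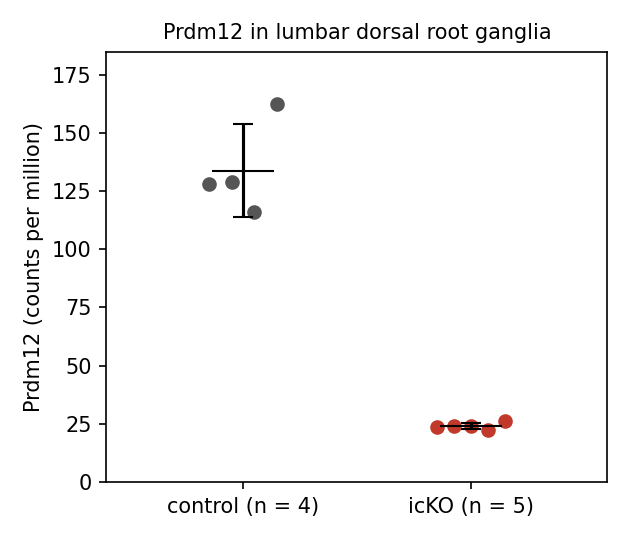
Prdm12 in CPM (vertical axis, from 0) for each of the 4 control and 5 icKO libraries, with the group mean and SD as horizontal and vertical bars. The icKO libraries lie between 22.3 and 26.2 CPM and the control libraries between 116 and 163 CPM.

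The comparison of icKO with control asked which other genes differed between the groups in adult ganglia. The controls are labelled wild type, so anything else that sets icKO mice apart from them cannot be told apart from loss of Prdm12. Of 17258 genes tested, 82 were higher and 65 lower in icKO by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and 1914 had an unadjusted p under 0.05. Of the 147, 139 were protein coding. The typical change was modest, with a median of 0.52 on the log2 scale for higher genes and 0.60 for the size of the change in lower genes. A log2 fold change over 1 in size was found for 17 higher and 11 lower genes. For all 147 genes the icKO and control libraries did not overlap, against 4.50% of all tested genes and 1.59% expected by chance. The 147 genes were picked for a difference between these same libraries, so their lack of overlap is no separate evidence. The number of higher genes was lowest at 45 without icKO 1, and fell without other libraries too. Calls in both directions numbered 89 without icKO 3 (61.8% higher), 92 without control 3 (59.8%), 94 without icKO 4 (62.8%) and 95 without icKO 5 (60%). The number of lower genes was 33 without icKO 1, 34 without icKO 3, 35 without icKO 4, 38 without icKO 5, 43 without control 1 and 37 without control 3. DESeq2 called 196 higher and 229 lower genes, among them all 145 of the 147 for which it gave an adjusted p.

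Among the higher genes, Chrna6 had the smallest adjusted p. Chrna6, which encodes an alpha subunit of nicotinic acetylcholine receptors, rose 2.62-fold from 94.3 ± 13.4 CPM (SD, n = 4) in control to 247 ± 26.6 CPM (SD, n = 5) in icKO. Its log2 fold change was 1.39 (SE 0.10), with an adjusted p of 5.44e-05 by edgeR's quasi-likelihood test. Chrna6 (ENSMUSG00000031491) lies on chromosome 8 from 27403212 to 27413944. Stk32a, a serine/threonine kinase gene on chromosome 18 from 43207583 to 43318682, rose from 18.4 ± 3.38 to 45.0 ± 2.84 CPM, with a log2 fold change of 1.29 (SE 0.10, adjusted p = 9.29e-05). Rgs9bp, whose product anchors a regulator of G protein signalling, had the largest log2 fold change of the 12 named higher genes at 2.16 (SE 0.21, adjusted p = 4e-04), at 4.92 ± 0.878 CPM against 1.11 ± 0.350 CPM. Skor2, a transcriptional corepressor of the SKI family, rose by 1.12 (SE 0.10), from 12.6 to 27.2 CPM. Receptor genes also included Cysltr2 for cysteinyl leukotrienes, at 1.11 (SE 0.12), and Agtr1a for angiotensin II, at 0.93 (SE 0.12). Genes of secreted proteins were Adamts19, a metalloprotease, at 1.58 (SE 0.25), and Ism1 at 1.04 (SE 0.10). Cfap206, a gene of cilia and flagella, rose by 1.03 (SE 0.10) from 13.3 to 27.2 CPM. Wscd1 at 1.41 (SE 0.17), Dcdc2a at 1.17 (SE 0.24) and the meiotic gene Mei1 at 1.09 (SE 0.18) completed the 12, at 2.55 to 4.26 CPM in icKO. Adjusted p over single libraries left out reached 0.0931 for Dcdc2a without icKO 1, with the call lost in all but 1 of the 9 cases (icKO 4), and 0.0539 for Mei1 without control 3, which also lost its call without icKO 1.

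Among the lower genes, Grik1 had the smallest adjusted p after Prdm12. Grik1, a kainate-type glutamate receptor subunit gene, fell from 414 ± 24.4 CPM (SD, n = 4) to 237 ± 8.54 CPM (SD, n = 5), with a log2 fold change of -0.81 (SE 0.06) and an adjusted p of 3.25e-05 by edgeR's quasi-likelihood test. It lies on chromosome 16 from 87895900 to 88290265. The insulin receptor-related receptor gene Insrr fell by 1.23 on the log2 scale (SE 0.15, adjusted p = 0.00174). Creg2, which encodes a secreted glycoprotein, fell from 34.7 ± 7.88 to 12.6 ± 2.55 CPM, a log2 fold change of -1.47 (SE 0.16, adjusted p = 0.000677), with control 1 at 46.5 CPM above the other control libraries at 30.05 to 32 CPM. The receptor genes Sstr1 for somatostatin and Mrgprb5, of the Mas-related family, had log2 fold changes of -1.54 (SE 0.30) and -1.40 (SE 0.25). Itgb6, an integrin beta subunit gene, was at -1.29 (SE 0.17), the adaptor gene Fyb2 at -1.43 (SE 0.27), and Kcng1, a modifier subunit of voltage-gated potassium channels, at -1.18 (SE 0.24). Lrrn4 at -1.11 (SE 0.22), the sulfotransferase gene Chst1 at -0.95 (SE 0.12) and the phospholipase C gene Plch2 at -0.88 (SE 0.13) were also among the 12. Leaving out icKO 1 ended the calls of Sstr1 (adjusted p = 0.103), Fyb2 (0.0835), Mrgprb5 (0.0602), Kcng1 (0.13) and Lrrn4 (0.105), and further libraries whose absence ended a call were icKO 3, 4 and 5 and control 3 and 4 for Sstr1, icKO 3, 4 and 5 and control 1 for Fyb2, icKO 3 and 4 and control 2 and 4 for Mrgprb5, icKO 2, 3 and 4 and control 1 and 4 for Lrrn4, and all but icKO 3 for Kcng1. Counts of Mrgprb5 are uncertain because related Mrgpr genes share sequence.

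**Figure D2:**
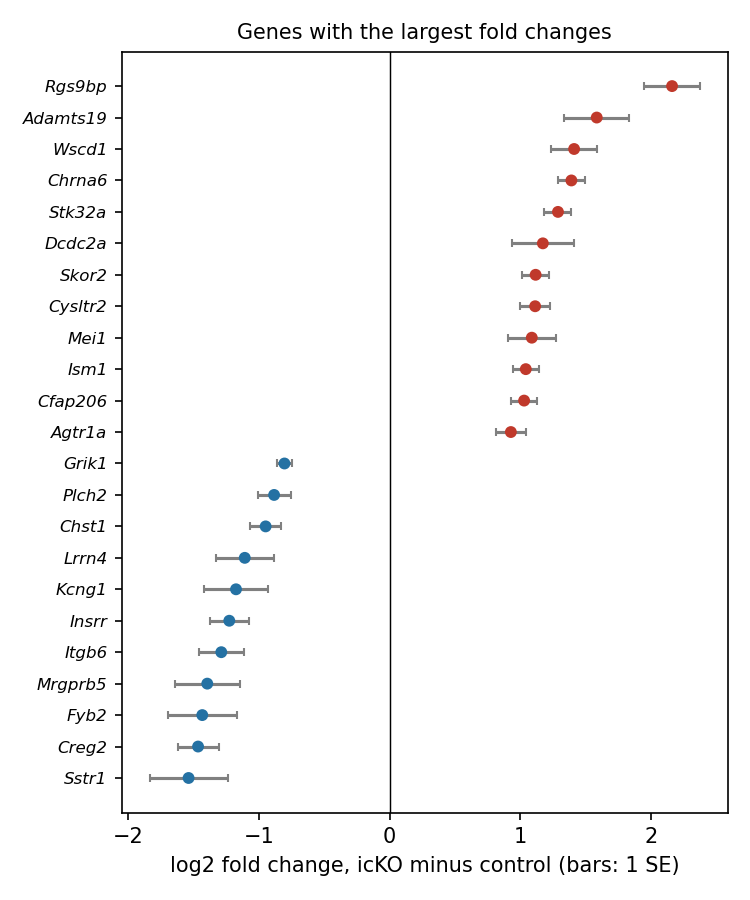
Log2 fold change of icKO minus control (horizontal axis) for the 12 higher genes (red) and 11 of the 12 lower genes (blue) with the largest changes apart from Prdm12, with bars of 1 SE. Values run from -1.54 for Sstr1 to 2.16 for Rgs9bp.

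Markers of itch-sensing non-peptidergic neurons were the group with the smallest camera p. Of 13 measured members, 3 rose, 1 fell and 9 did not pass over all genes tested, while 9 were higher and 2 lower adjusted over the list alone. The risers were Cysltr2, from 14.98 ± 1.83 to 32.4 ± 4.76 CPM, Agtr1a, from 24.8 ± 4.83 to 47.1 ± 4.41 CPM, and Npy2r, a neuropeptide Y receptor gene, from 39.9 ± 4.41 to 53.3 ± 2.69 CPM. Their adjusted p-values by edgeR's quasi-likelihood test were 0.000592, 0.00208 and 0.0178. Mrgprb5 fell from 9.92 ± 3.75 to 3.74 ± 0.901 CPM (adjusted p = 0.0194). The median log2 fold change of the list was 0.49. Camera gave the list an adjusted p of 3.2e-11 upward with the preset correlation, and an adjusted p of 0.12 with an estimated correlation. The list had medians of 0.56 within the 4 libraries with high Y-linked counts and 0.49 within the 5 with low ones. Npy2r lost its call without icKO 1 (adjusted p = 0.0578) and without control 3.

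Peptidergic nociceptor genes moved in both directions. Of 12 measured, 2 fell, among them Gfra3, a receptor gene for the growth factor artemin, 1 rose, Calcb, and 9 did not pass, with 2 higher and 5 lower adjusted over the list alone. Gfra3 went from 68.5 ± 13.9 to 43.3 ± 4.57 CPM, a log2 fold change of -0.66 (SE 0.12) with an adjusted p of 0.0252 by edgeR's quasi-likelihood test, and Calcb, a calcitonin gene-related peptide gene, from 164 ± 11.8 to 235 ± 15.6 CPM, a log2 fold change of 0.52 (SE 0.07, adjusted p = 0.00253). Ptgir, the prostacyclin receptor gene, did not pass at -0.37 (SE 0.11, adjusted p = 0.157), with control 1 at 103 CPM above the other control libraries at 71.8 to 74.7 CPM. Camera gave the list an adjusted p of 0.0375 downward with the preset correlation and an adjusted p of 0.888 with an estimated correlation. The list call was lost without icKO 3 (adjusted p = 0.165), icKO 5, control 1 or control 4, and that of Gfra3 was kept only without icKO 2 or control 2 (highest adjusted p 0.0761, without icKO 3). Of the 12 measured genes of Mrgprd-type non-peptidergic nociceptors, 0 passed with edgeR's test, and 1 was higher and 1 lower at an unadjusted p under 0.05. Examples were Ret at -0.32 (SE 0.10, adjusted p = 0.213), Lpar3 at 0.24 (SE 0.09, 0.331), P2rx3 at 0.19 (SE 0.10, 0.504) and Scn11a at -0.13 (SE 0.09, 0.662), and camera gave the list an adjusted p of 0.711.

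Among 29 ion channel genes of sensory neurons, 3 fell and 26 did not pass, with 2 higher and 7 lower adjusted over the list alone. The cold-activated channel gene Trpm8 fell from 47.3 ± 7.78 to 30.01 ± 1.31 CPM, the serotonin-gated channel gene Htr3a from 150 ± 16.4 to 101 ± 10.3 CPM, and the acid-sensing channel gene Asic1 from 80.3 ± 4.10 to 53.3 ± 9.51 CPM. Adjusted p-values were 0.00559, 0.0074 and 0.0257 by edgeR's quasi-likelihood test. Piezo2, a mechanically activated channel gene, was at 0.33 (SE 0.08) and did not pass (adjusted p = 0.0711). Camera gave the list an adjusted p of 0.00933 downward with the preset correlation and an adjusted p of 0.888 with an estimated correlation. The list call was lost without control 4 (adjusted p = 0.161) or control 1, and the Asic1 call without control 3 (adjusted p = 0.0853), control 1, control 4, icKO 1 or icKO 5. Of 8 genes of C-LTMR and cold-sensing neurons, Tafa4 (listed as Fam19a4) rose from 53.3 ± 4.42 to 68.5 ± 2.24 CPM (adjusted p = 0.0125) and Trpm8 was the gene that fell, while Th at 0.23 (SE 0.08) and P2ry1 at 0.21 (SE 0.09) did not pass. Adjusted over the list alone, 2 were higher and 1 lower, and camera gave an adjusted p of 0.0547, or a call upward without icKO 1 (adjusted p = 0.028), icKO 2 (0.0342) or control 4 (0.000209).

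Of 15 genes of A-fibre mechanoreceptors and proprioceptors, 1 rose, 0 fell and 14 did not pass, with 1 higher and 6 lower adjusted over the list alone and 8 lower at an unadjusted p under 0.05. The riser was Ntrk3, the neurotrophin-3 receptor gene, from 374 ± 67.2 to 527 ± 18.5 CPM, a log2 fold change of 0.49 (SE 0.10) with an adjusted p of 0.0342 by edgeR's quasi-likelihood test. The potassium channel gene Kcnc1 was at -0.58 (SE 0.12, adjusted p = 0.0517), with icKO 4 at 45.2 CPM below the other icKO libraries. The transcription factor gene Etv1 was at -0.39 (SE 0.08, adjusted p = 0.0525) and the neurofilament gene Nefh at -0.36 (SE 0.08, adjusted p = 0.0763). The list median was -0.21, and camera gave an adjusted p of 4.91e-05 downward with the preset correlation and an adjusted p of 0.298 with an estimated correlation. The Ntrk3 call was lost without icKO 1 (adjusted p = 0.0969), icKO 3, icKO 4, icKO 5, control 1 or control 3.

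Of 14 measured neuropeptide genes, Calcb rose and 13 did not pass, with 5 higher and 0 lower adjusted over the list alone. Cartpt was at 0.60 (SE 0.18, adjusted p = 0.183 by edgeR's quasi-likelihood test), the substance P precursor gene Tac1 at 0.37 (SE 0.12, adjusted p = 0.25) and the somatostatin gene Sst at 0.66 (SE 0.23, adjusted p = 0.273). Camera gave the list an adjusted p of 0.00106 upward with the preset correlation and an adjusted p of 0.37 with an estimated correlation. Of 28 G protein-coupled receptor genes, Npy2r rose and 27 did not pass, with 4 higher and 4 lower adjusted over the list alone. Mrgpre was at 0.30 (SE 0.07), the serotonin receptor gene Htr1f at 0.53 (SE 0.13) and Mrgprx1 at -0.30 (SE 0.07), with adjusted p-values of 0.07, 0.0788 and 0.081. Camera gave that list an adjusted p of 0.711 upward, although its mean was -0.01. For changes in either direction, fry gave it an adjusted p of 1.01e-05, the smallest of the 27 lists.

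**Figure D3:**
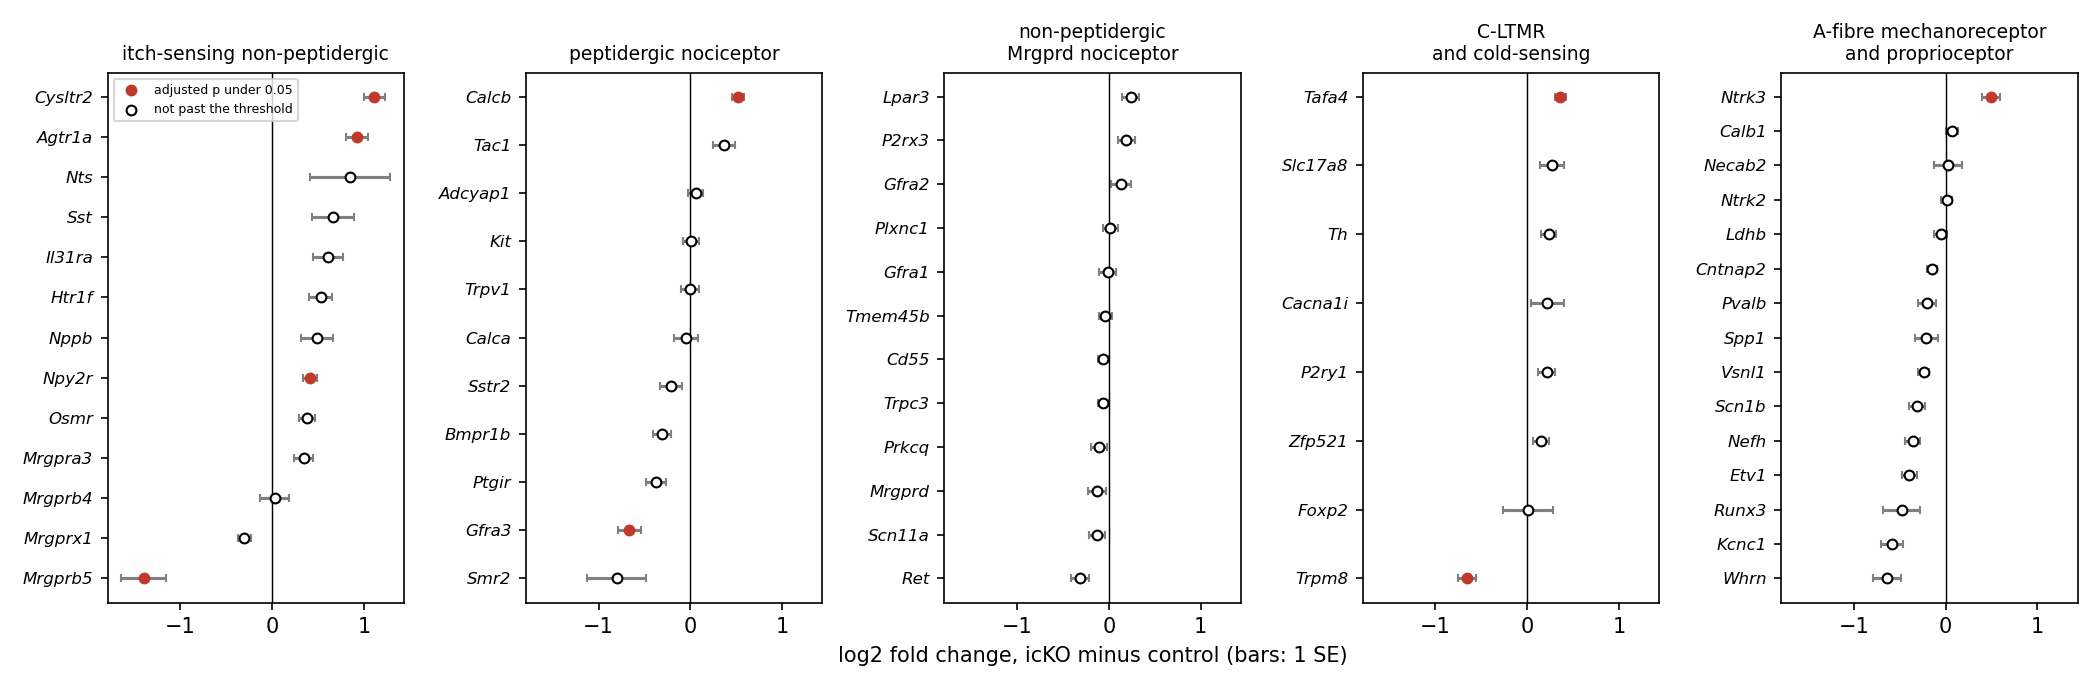
Log2 fold change of icKO minus control (horizontal axis, bars of 1 SE) for the measured members reported here of 5 lists of sensory neuron genes, with filled red points for genes past an adjusted p of 0.05 and open points for the others. Of the 13 itch-sensing genes 11 lie above 0, and of the 15 A-fibre genes 11 lie below 0.

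No sensory neuron transcription factor passed among 24 measured with edgeR's quasi-likelihood test, where 2 were higher and 5 lower at an unadjusted p under 0.05 and 2 were lower adjusted over the list alone. Besides Etv1, the smallest adjusted p-values belonged to Maf at -0.25 (SE 0.07, adjusted p = 0.146), Ldb2 at 0.20 (SE 0.06, 0.224) and Shox2 at -0.37 (SE 0.14, 0.299). Camera gave the list an adjusted p of 0.638 downward, although its median was 0.02. Over single libraries left out, the median ranged from -0.05 (without control 2) to 0.09 (without control 4, where camera pointed upward). Determinants of visceral and other lineages had 7 measured genes and 0 passed, with 1 higher at an unadjusted p under 0.05. That gene was Nkx6-2, at 1.81 ± 0.352 CPM in icKO and 0.933 ± 0.200 CPM in control (log2 fold change 0.96, SE 0.21, adjusted p = 0.0607), and it was the 1 member that passed adjusted over the list alone. The others named were Ebf1 at 0.11, Isl2 at -0.11 and Pax2 at 0.28, and the list had an adjusted camera p of 0.458 upward with a median of -0.08. That median lay above 0 without control 3 (0.09) or control 4 (0.02) and below 0 without any other single library. Of 15 genes of the Prdm family and its G9a partners, 0 passed and 0 had an unadjusted p under 0.05 with edgeR's test. Prdm8 at 0.20, Ehmt1 at 0.06, Prdm6 at 0.64 and Prdm10 at -0.06 had the smallest adjusted p-values, from 0.494 to 0.795, and camera gave 0.758.

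General neuronal, injury and activity genes gave no call with edgeR's test. Among 10 pan-neuronal genes, 1 was higher and 1 lower at an unadjusted p under 0.05 and 1 was higher adjusted over the list alone. Syt1 was at 0.31 (SE 0.08, adjusted p = 0.112), Nefm at -0.27 (0.306), Rbfox3 at -0.18 (0.53) and Nefl at -0.14 (0.594), the last with control 4 at 2818 CPM below the other control libraries at 3667 to 3742 CPM, and camera gave the list an adjusted p of 0.553. Of 18 nerve injury genes 1 was higher at an unadjusted p under 0.05, and the log2 fold changes were 0.36 for Flrt3, -0.29 for Csf1, -0.20 for Gadd45a and -0.15 for Hspb1. Camera gave the injury list an adjusted p of 0.896 with a median of -0.04, but called it upward without control 1 (median 0.27, adjusted p = 0.00338). Of 12 immediate early genes 1 was lower at an unadjusted p under 0.05, with Arc at -0.43 (SE 0.12, adjusted p = 0.164), Egr1 at -0.57 (0.525), Nr4a1 at -0.17 (0.726) and Egr2 at -0.21 (0.738), and camera gave an adjusted p of 0.127, or 0.00756 downward without icKO 1. Egr1 was at 47.3 CPM in control 3 and at 15.5 to 20.1 CPM in the other control libraries.

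All 9 measured lymphocyte and neutrophil genes had fitted log2 fold changes above 0. Of these 0 passed with edgeR's quasi-likelihood test, while 4 were higher at an unadjusted p under 0.05 and adjusted over the list alone, all 4 of them genes of neutrophil granules or cytoplasm. S100a9 was at 13.7 ± 4.80 CPM in icKO and 7.84 ± 1.59 CPM in control (adjusted p = 0.141), Camp at 3.47 and 1.94 CPM (0.171), S100a8 at 8.37 and 4.79 CPM (0.183), and Ngp at 7.42 and 4.28 CPM (0.213). Camera gave the list an adjusted p of 0.000132 upward with the preset correlation and an adjusted p of 0.37 with an estimated correlation. The list median was 0.57, and 0.38 without control 1. The 6 erythroid genes had a median of 0.64 and 0 of them passed or had an unadjusted p under 0.05, with Hbb-bs at 0.71, Hbb-bt at 0.81 and Alas2 at 0.57, and camera gave adjusted p-values of 0.0219 and, with an estimated correlation, 0.888. Globin counts are uncertain because the copies share sequence, and the erythroid call was lost without control 1 (adjusted p = 0.14), control 2, icKO 1, icKO 4 or icKO 5. The erythroid median was 0.39 without icKO 1, 0.41 without control 1 and 0.98 without control 3. Summed over the list, lymphocyte and neutrophil genes made 36.9 ± 11.7 CPM (SD, n = 5) in icKO and 21.6 ± 4.73 CPM (SD, n = 4) in control. The exact permutation test gave p = 0.0476 unadjusted and 0.667 adjusted over 14 measures of composition, none of which passed. The smallest p this permutation test allows is 0.00794, so a difference in a single measure could not have passed after adjustment over 14. The lack of a pass therefore does not show equal composition.

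Skeletal muscle genes differed between single libraries more than between groups. Acta1 was at -1.20 (SE 0.49), Mylpf at -0.94, Myh1 at -1.48 and Ckm at -1.08, and 0 of 8 measured genes passed with edgeR's test, with 1 lower at an unadjusted p under 0.05. Camera gave the muscle list an adjusted p of 0.0248 downward and, with an estimated correlation, 0.888. Summed muscle genes reached 67.2 CPM in control 2 and 39.7 CPM in icKO 1. Without control 2 the list median was 0.18, with camera still pointing downward (adjusted p = 0.632), and the call was also lost without icKO 2, icKO 3, icKO 4 or icKO 5. Without icKO 1 the median was -2.27 (adjusted p = 1.07e-06). Of the 5 adipocyte genes 0 passed or had an unadjusted p under 0.05 (Adipoq -1.16, Retn -0.88, Plin1 -1.20, Cfd -0.78, adjusted camera p 0.0547), and camera called the list downward without icKO 1 (adjusted p = 0.0256), control 2 (0.00119) or control 4 (0.0402). The 3 measured spinal cord genes Gfap, Mobp and Aqp4 were at -2.33, -1.12 and -0.35 and did not pass (Gfap was lower at an unadjusted p of 0.0264 with edgeR's test), with an adjusted camera p of 0.383, and the sum over the whole spinal cord list, genes too low to test included, was 68.8 CPM in control 4 against 12.8 to 15.7 CPM in the other control libraries. Without control 4 the spinal cord list turned upward, with a median of 0.56 against -1.12 over all libraries (adjusted p = 0.133).

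Markers of satellite glia, Schwann cells, macrophages, interferon response, vessels and fibroblasts gave no call among genes or lists over all 9 libraries, but some of these lists were called without a single library. At an unadjusted p under 0.05 with edgeR's test, 1 Schwann cell, 1 interferon response and 1 vascular gene were higher (Mlip, Bst2 and Tagln) and 1 satellite glia gene (Kcnj10) and 1 Hox gene (Hoxd8) were lower. Adjusted camera p-values were 0.711 for satellite glia, 0.852 for myelinating Schwann cells, 0.091 for macrophages, 0.383 for interferon response, 0.711 for endothelial and mural cells and 0.127 for fibroblasts and meninges. Camera called the macrophage list upward without icKO 1 (adjusted p = 0.015), icKO 2 (0.0313), control 2 (0.0215) or control 3 (0.00306), the interferon list without icKO 1 (0.015) or control 1 (0.0452), and the fibroblast list without icKO 2 (0.00152). Satellite glia genes included Kcnj10 at -0.20, Aldoc at -0.14, Apoe at 0.13 and Slc1a3 at 0.07. Schwann cell genes included Mlip at 0.38, Pmp22 at 0.09, Pllp at -0.17 and Egr2, and the median of that list was below 0 while camera pointed upward. Macrophage genes included H2-Aa at 0.35, Cd68 at 0.26, Trem2 at 0.41 and Cd74 at 0.23, and interferon response genes Bst2 at 0.32, Ifit1 at 0.51, Mx1 at -0.50 and Usp18 at 0.28. Vascular genes included Tagln at 0.57, Tek at 0.28, Pdgfrb at 0.09 and Des at -0.20, and fibroblast genes Col3a1 at 0.57, Col1a2 at 0.25, Slc6a13 at 0.34 and Igf2 at 0.65. Among 18 Hox genes of axial level, Hoxd8 was at -0.29, Hoxa9 at -0.18, Hoxb8 at -0.24 and Hoxb9 at -0.29, with an adjusted camera p of 0.185 and a median of -0.09. Without control 1 the Hox list was called downward, with a median of -0.22 (adjusted p = 2.48e-05). The 7 measured genes of the mitochondrial genome had an adjusted camera p of 0.553, with mt-Co1 at 0.08, mt-Cytb at 0.06, mt-Nd1 at 0.06 and mt-Nd5 at 0.05. The mitochondrial share of counts was 3.01 ± 0.445% (SD, n = 5) in icKO and 2.87 ± 0.526% (SD, n = 4) in control.

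Of the 27 lists, 8 were called by camera with the preset correlation, 4 upward and 4 downward, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. Fry called 0 lists for a change one way, with 4 at an unadjusted p under 0.05, and 9 for changes in either direction. Across these lists, the called members named here were Mrgprb5, Gfra3, Trpm8, Htr3a and Asic1, which were lower, and Calcb, Cysltr2, Agtr1a, Npy2r, Ntrk3 and Tafa4, which were higher in icKO.

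The libraries also differed in sex-linked genes. The Y-linked gene Ddx3y was at 72.8 and 58.4 CPM in icKO 1 and 2 and at 64.9 and 41.9 CPM in control 1 and 3, where Xist, the RNA of the inactive X chromosome, lay between 0.77 and 1.11 CPM. In icKO 3, 4 and 5 and in control 2 and 4, Xist lay between 311 and 396 CPM. In icKO 4, Ddx3y was at 2.01 CPM, above the 0 to 0.15 CPM of the other libraries with high Xist. The Prdm12 log2 fold change was -2.35 (SE 0.08) within the 4 libraries with high Y-linked counts and -2.59 (SE 0.12) within the other 5. In those smaller fits edgeR's test called 0 higher and 3 lower genes (Prdm12, Grik1 and Gm13425) and 11 higher and 9 lower genes. At an unadjusted p under 0.05, 786 genes were higher and 715 lower in the first, and 526 higher and 434 lower in the second. Without icKO 4 and control 4, a choice made after seeing the data, 59 genes were higher and 39 lower.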

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

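All values here were picked by a test of single libraries that lie far from the others of their group. Of 274 groups of values tested, 26 had such a library, and about 13.7 were expected by chance. Control 4 held 6 of the 26 and icKO 1 held 5. Sums of lists were tested beside their own member genes, so the 26 are not independent of one another.

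In control 4 the markers of spinal cord stood out. Gfap, an astrocyte gene, was at 29.7 CPM against 0.449 to 1.47 CPM in the other control libraries, Mobp, an oligodendrocyte gene, at 3.40 against 0.182 to 0.408 CPM, and Aqp4 at 34.2 against 10.9 to 14.2 CPM. The sum of the spinal cord list was 68.8 CPM against 12.8 to 15.7 CPM. In the same library the neurofilament gene Nefl was at 2818 CPM against 3667 to 3742 CPM, and the summed pan-neuronal genes at 16860 CPM against 19730 to 19870 CPM. Mobp was also set apart in icKO 5, at 0.908 CPM against 0.271 to 0.411 CPM.

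Muscle genes stood out in icKO 1 and control 2. In icKO 1, Acta1 was at 7.70 CPM against 1.98 to 3.04 CPM in the other icKO libraries, Mylpf at 2.42 against 0.731 to 1.08 CPM, Ckm at 2.83 against 0.271 to 0.632 CPM, and the summed muscle list at 39.7 against 5.04 to 7.24 CPM. In control 2, Myh1 was at 3.27 CPM against 0.309 to 0.660 CPM and the summed list at 67.2 against 7.84 to 17.8 CPM. The adipocyte gene Retn was at 0.875 CPM in icKO 1 against 0.197 to 0.329 CPM. The Schwann cell list gene Mlip was at 28.3 CPM in control 2 against 19.0 to 20.5 CPM.

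In control 1, Creg2 was at 46.5 CPM against 30.05 to 32 CPM, Ptgir at 103 against 71.8 to 74.7 CPM, and the interferon response gene Ifit1 at 53.3 against 26.3 to 29.8 CPM. The summed fibroblast and meninges list was at 752 CPM there against 1477 to 1583 CPM. Ifit1 was also high in icKO 2, at 86.2 CPM against 35.7 to 45.2 CPM, as was Gadd45a, at 18.2 against 12.05 to 13.46 CPM. Egr1, an immediate early gene, was at 47.3 CPM in control 3 against 15.5 to 20.1 CPM. Th was at 190.2 CPM in icKO 3 against 174 to 178 CPM. In icKO 4, Kcnc1 was at 45.2 CPM against 58.5 to 63.3 CPM, the 10 most counted genes took 5.01% of counts against 4.36 to 4.48%, and the summed endothelial and mural list was at 405 CPM against 302 to 326 CPM.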

How the results depend on the processing

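The Prdm12 decrease passed in every fit run, with log2 fold changes from -2.53 (without control 3) to -2.37 (without control 4) on leaving out single libraries. Of the 24 genes named by size of change, 17 kept their call without each library in turn. No scaling moved the median of all genes by over 0.1 on the log2 scale. Fits within Y-linked classes, with fibroblast or erythroid covariates, and without icKO 4 and control 4 were chosen after seeing the data. The cause of the differences below was not tested, except that fewer libraries, fewer or more genes tested and other thresholds follow from the settings themselves.

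Higher and lower genes numbered 172 and 221 with no count filter, 196 and 229 with DESeq2, 142 and 150 at an adjusted p under 0.1, 39 and 24 under 0.01, and 17 and 11 with a log2 fold change over 1 in size. The share of higher genes among calls was 43.8% with no count filter and 46.1% with DESeq2, against 55.8%. With the replicate number as a block, 28 genes were higher and 20 lower, and 45 of the 147 calls remained. No control library shares the number of icKO 5, so that fit took no information on the change from icKO 5. The block terms also left fewer degrees of freedom, so the lost calls do not show that the numbers matter. Expression gave no clear sign that the numbers pair the libraries. Deviations of 2 of 4 same-numbered pairs were correlated over 0.1 (0.103, -0.175, -0.0441 and 0.170), and 0 icKO libraries correlated best with their own number. These correlations could not rule out a preparation step shared by number. Within libraries of high Y-linked counts 0 genes were higher and 3 lower, and within those of low counts 11 and 9. Lower genes numbered 42 with the erythroid covariate and 39 without icKO 4 and control 4. Over single libraries left out, higher genes ranged from 45 (without icKO 1) to 85 (without control 2) and lower genes from 33 (without icKO 1) to 90 (without control 2).

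The number of called lists was 5 with at least 1 CPM in 4 libraries, 0 with an estimated correlation, 0 with fry, and 5 (without icKO 5) to 12 (without icKO 1) over single libraries left out. Of the 8 called lists, camera's direction turned for the erythroid list with its own level as covariate, with a median of 0.0246, and for the muscle list within libraries of high Y-linked counts, with a median of 0.81, against -2.89 (adjusted p = 2.04e-14) within those of low counts. The ion channel median of -0.09 was -0.05 without control 1, -0.04 without control 4 and -0.14 without control 2, and the neuropeptide median of 0.21 was 0.32 without control 1 and 0.14 without control 3. Of the 19 lists not called, 10 were called in at least 1 alternative, 8 of them without a single library. Camera's direction turned in at least 1 alternative for 15 of the 19, among them the spinal cord list without control 4, and 1 of these, the injury list, was called upward, without control 1 (median 0.27) and with the fibroblast (0.21) and erythroid (0.23) covariates. The Hox list was called with both covariates (adjusted p = 0.00831 and 0.00238) and within libraries of low Y-linked counts (0.00662). With the replicate block camera also called the C-LTMR, adipocyte and macrophage lists, the last with an adjusted p of 0.0142, and no longer the peptidergic list (0.156). Genes near 1 CPM rest on about 20 to 30 counts per library.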

Other observations

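The tests of neuron composition and of DNA from another strain, and the fits with fibroblast or erythroid covariates and within Y-linked classes, were chosen after the results were seen, as were the genes of the next paragraph.

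Pdx1, a homeobox transcription factor gene of pancreas development, had 80 counts over the 5 icKO libraries, 7 to 21 in each, and 0 in the 4 control libraries. Against a floor of 3 counts over the control group it was at least 19.8-fold higher, with an adjusted p of 0.00407 by edgeR's quasi-likelihood test. Drd1, the dopamine D1 receptor gene, was at 1.55 ± 0.506 CPM (SD, n = 5) and 0.215 ± 0.0802 CPM (SD, n = 4), a log2 fold change of 2.78 (SE 0.33, adjusted p = 0.00144 by the same edgeR test). The nicotinic receptor gene Chrna7 fell, from 64.3 ± 16.1 to 38.3 ± 5.56 CPM (log2 fold change -0.75, SE 0.14, adjusted p = 0.0292), while Chrna6 rose. The serotonin receptor gene Htr5b rose from 9.09 ± 1.40 to 14.7 ± 1.45 CPM (log2 fold change 0.69, SE 0.11, adjusted p = 0.0129). Gm13425, the antisense gene over the 5′ end of Prdm12 on chromosome 2, was at -0.95 (SE 0.13, adjusted p = 0.0042). Its annotated span overlaps that of Prdm12, and where its reads lie was not examined.

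Of the 13 protein-coding mitochondrial genes, 6 had almost no counts. Over all 9 libraries mt-Co2 and mt-Atp6 had 1 count each, mt-Co3, mt-Atp8 and mt-Nd4l 0, and mt-Nd3 59, against 2022622 for mt-Co1 and 1623475 for mt-Cytb. The mitochondrial share of counts above leaves these 6 genes out in effect.

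Whether any grouping of the libraries would give as many calls was examined with 100 splits, the real one included. The 82 higher genes compared with at most 6 in any other split examined and the 65 lower genes with at most 7. Only 1 of the 100 splits, the real one, gave as many in each direction, so a chance split of these libraries was unlikely. The splits treat the libraries as separate animals, which the labels do not state. The 8 called lists did not stand apart, since 82 of 100 splits called as many and another split called 18, so chance was not excluded for the number of lists. The A-fibre list had a camera p as small in 4 of 100 splits (3.63e-06, smallest other 5.92e-07), few for this list alone, but chance was not excluded for a list picked from 27. For the other called lists outside the patterns below chance was not excluded either, with a camera p as small in 12 of 100 splits for neuropeptides, 23 for peptidergic nociceptors, 30 for ion channels, 41 for erythroid and 48 for skeletal muscle genes.

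The itch-sensing list was the first pattern weighed, with 11 of 13 genes above 0. Of the 13 genes, 7 were also in another list. The camera p of 1.18e-12 was reached by 2 of 100 splits (smallest other 1.76e-13), few for this list alone, but chance was not excluded for the smallest p of 27 lists. The tables argue against connective tissue as the source, with a median of 0.43 after the fibroblast covariate against 0.49 before, and against the mix of sexes, with medians of 0.49 and 0.56 within the Y-linked classes. More itch-sensing neurons of every kind may contribute and stay open. A permutation test that the 13 genes share 1 change gave p = 0.00794, the smallest possible, with or without the 4 Mrgpr genes. It weighted genes by their SE in the real groups, which may favour the real split, so that p is not exact. The genes below 0 were Mrgprb5 and Mrgprx1, whose counts are uncertain, and genes that other cells also express would rise less. More Nppb-class neurons also stay open, with all 7 class genes above 0 (0.38 to 1.11) but a permutation p of 0.00794, weighted in the same way, for 1 shared change. A change of these genes within neurons that lost Prdm12 also stays open as a hypothesis and was not tested, since whole ganglia do not tell cells apart.

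The lymphocyte and neutrophil list was the second pattern, with a median of 0.57 over 9 genes, none of them in another list. The 4 neutrophil genes lay at 0.79 (Ngp) to 0.83 (Camp), and the 5 T and B cell genes at 0.06 (Cd79b) to 0.57 (Cd3g), none of these 5 with an unadjusted p under 0.05 in edgeR's test. A camera p as small was found in 10 of 100 splits (1.47e-05, smallest other 2.78e-11), so chance was not excluded. The mix of sexes is argued against by medians of 0.61 and 0.77 within the Y-linked classes. More blood left in the icKO ganglia may contribute and cannot be told apart from a change in the tissue. With the erythroid covariate the median went from 0.57 to 0.276, under the bound of 0.287 set for this explanation before that fit. It lay under the bound by 0.0111, less than the SD of the members over the square root of their number (0.0945). That margin was not part of the rule set before. It treats the members as independent and leaves out the spread between libraries.

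Called genes that lie beside one another were the third pattern, with 14 pairs within 1 Mb, 12 of them changed in the same direction, such as Isoc1 with Adamts19. Of the 14 pairs, 1 lay within 10 Mb of Prdm12, that of Prdm12 itself with Gm13425, and 0 of the other 13 did. Within 10 Mb of Prdm12, 2 of 265 tested genes were called, these same 2, against 2.26 expected from the share over all genes. This argues against DNA of another strain around the Prdm12 allele as a source of many calls. DNA carried at other places in the genome was not examined. Chance placement is consistent with the number, since a share of 0.789 of 10000 random sets of tested genes of like expression had as many pairs, with a median of 17. Whether shared direction within pairs exceeds chance was not tested.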
